A study of Xenopus laevis with 7 samples.

How the data were processed

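The series holds RNA sequencing of Xenopus laevis embryos at stage 10.5: 1 library of whole embryos, 3 of dorsal lips and 3 of ventral lips. Per the labels' protocols, frogs came from a commercial supplier, lips were dissected in Barth's saline, and libraries were made from polyadenylated RNA with a TruSeq kit and sequenced as single-end reads on a HiSeq instrument. The group and replicate number of each library come from its title. Per the file headers, the numbers mark experiments, the whole embryo library belongs to experiment 1, and the 4 libraries of experiments 2 and 3 shared a sequencing lane.

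The expression values are RPKM per transcript, deposited by the authors for 44421 transcripts. Per the submitters' processing notes TopHat2 2.09 and DESeq were used, without a stated role for each. Per the file headers the reads were set against the JGI 9.1 gene models of Xenopus laevis, and human symbols were assigned by protein BLAST. The counter, the strand setting and the treatment of reads that fit several transcripts are not given in the sources used here. Reads shared between L and S copies or tandem copies, such as those of Xnr3 and VENTX, could therefore be placed on the wrong copy, left out or counted for more than 1 copy. Differences between such copies are uncertain to that degree. The adjusted p-value beside the RPKM values is deposited by the authors and rests on the libraries of experiments 2 and 3, per the file headers. The ratio in the tables of dorsal and ventral transcripts is deposited by the authors and rests on the same 4 libraries, and the ratio in the injury table is that of each lip to the whole embryo in experiment 1, per the file headers. The libraries behind the ratio in the signature tables are not given in the sources used here. The correlation coefficients to chordin and bambi are a score deposited by the authors, taken over samples that include kinds not analysed here, per the file headers, and the kind of coefficient is not stated. The title of the authors' deposited ventral table states another number of entries than the 94 it holds, and the largest adjusted p in it is 0.0553.

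Depth was recovered from the values. Within a library, RPKM values of a transcript are whole multiples of what 1 read is worth, and the steps gave whole reads within a tolerance of 0.001 reads for all but 1 of the 35326 transcripts above 0. The recovered reads sum to between 26373698 and 37880460 per library, and the mapped reads by which the authors scaled the RPKM values lie between 27083637 and 38903417. Transcript lengths were recovered in the same step.

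The design was fixed for counts or for normalised values before the data were examined. Since the values are RPKM, the test for normalised values was used: limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) on log2(RPKM + 0.5), for transcripts with a mean of at least 1 RPKM over the 6 lip libraries, with Benjamini-Hochberg adjustment over the 16514 transcripts and a threshold of 0.05. Fold changes are dorsal minus ventral on that scale, which understates the change of transcripts near 0. No block was used in the planned fit, and a fit with the experiment number as a block was set beside it, also before the data were examined. Whether the numbers pair the libraries was checked before the calls were compared. Across transcripts, the deviations of same-numbered dorsal and ventral libraries from their group means correlated at 0.926, 0.881 and 0.819, so the numbers were taken to pair the libraries and blocked values are given beside results that they change. The lips of experiments 2 and 3 also correlated across numbers, at 0.748 and 0.839, the latter above the 0.819 of a same-numbered pair, so these 2 experiments lie close to each other. With experiment 1 set far apart, the check cannot tell whether the numbers pair the libraries within experiments 2 and 3.

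Gene lists were tested with camera (preset correlation 0.01, then with an estimated correlation) and fry, adjusted over the 13 lists, and their members were counted past the test over all genes and adjusted over the list alone. The lists were: Spemann organizer, ventral center and BMP synexpression, zygotic Wnt targets and posterior genes, pan-mesodermal genes, Nodal and activin signalling, FGF signalling, endoderm, neural ectoderm, epidermal and superficial epithelium, germ plasm and vegetal maternal RNA, retinoic acid pathway, convergent extension and axial mesoderm, and ribosomal proteins. Some genes are in more than 1 list. Members were matched by the frog symbol, or by the human symbol where the file gives only a transcript number or a placeholder name, so that paralogs with the same human match can stand under a single name. That the file writes Xnr3 and Siamois in its own way was settled after seeing the names and before any test. Of 14204 transcripts with their own symbol and an L or S suffix, 11762 have that symbol in an NCBI RefSeq gene table of another assembly (v10.1), used for names alone, and no coordinates are given. Homeolog pairs were tested with limma on the L minus S difference of log2(RPKM + 0.5) for 3301 pairs with both copies at a mean of at least 1 RPKM.

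The transcripts named in the text follow a rule fixed before the data were examined: the 8 with the largest log2 fold change in each direction among those past the test with no overlap of the groups and at least 5 RPKM in the higher group, the 3 members of each list with the smallest p, and the 3 homeolog pairs with the smallest p in each direction. Other names are list members or were chosen after their values were seen, as stated beside them.

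The alternatives were the block, leaving out each lip library in turn, pseudocounts of 0.1 and 1, no filter or a mean of at least 5 RPKM, quantile normalisation, limma without trend, and L and S values summed. Added after seeing the data were experiments 2 and 3 alone and limma voom on recovered reads, each with and without the block. The steps were tested on simulated data with known changes. Without the block, limma recovered 3.03% of transcripts changed 2-fold and 73% of those changed 8-fold among 16487 simulated transcripts, with 0 false calls. With the block it recovered 100% of both, with 16 false among 215 calls. For 4-fold changes of the L copy in 3294 simulated pairs it recovered 76% without and 100% with the block. Apart from the known changes, both simulated lips of an experiment had the same mean, a setting that favours the block. The real libraries also held shifts of a single lip in a single experiment, so recovery with the block does not give the power of the real blocked fit. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps. The whole embryo library entered no test, because it has no replicate.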

Results

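Messenger RNA was sequenced from early gastrulae of the African clawed frog Xenopus laevis at stage 10.5, when the blastopore lip has formed and cells are moving inside the embryo. The 7 libraries came from 1 sample of whole embryos, 3 samples of dorsal lips and 3 samples of ventral lips. The dorsal lip holds the Spemann organizer, the signalling tissue that patterns the body axis, and the ventral lip holds the opposing center marked by BMP signalling. The whole embryo library held 37880460 recovered reads. The dorsal lip libraries held 33990263, 31135424 and 30914302 and the ventral lip libraries 34264229, 30537195 and 26373698, so that 1 read over 1 kb was worth between 0.0257 and 0.0369 RPKM, the unit of reads scaled to transcript length and mapped reads. The labels do not say that replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

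The lip libraries differed more by experiment than by side of the embryo. The first principal component held 75.9% of the variance and set both lips of experiment 1 apart from those of experiments 2 and 3. The second held 18.8% and separated dorsal from ventral lips in each experiment. Same-side libraries of experiments 2 and 3 correlated at 0.993 or more across transcripts, which are not independent replicates, and those of experiment 1 correlated with them at 0.897 to 0.926. Of 16514 transcripts tested, 3009 lay over 2 times apart between the lips of experiment 1 and those of experiments 2 and 3. Because of this spread, each comparison is given without and with the experiment number as a block.

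**Figure D1:**
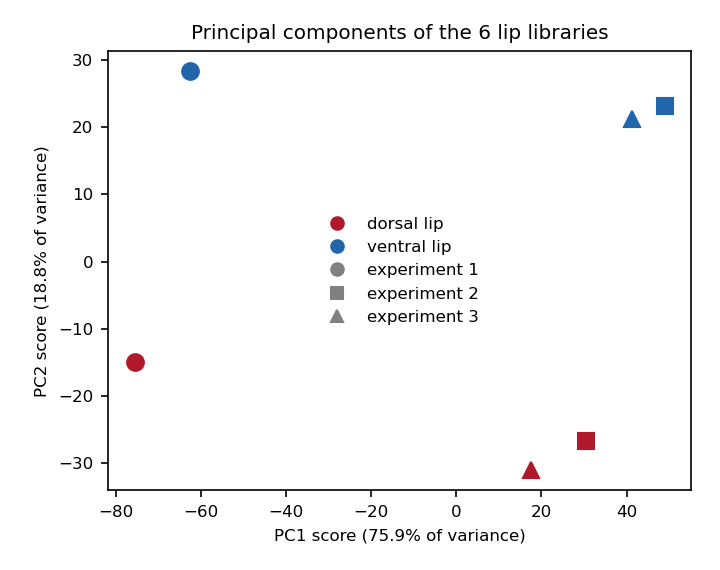
Scores of the 6 lip libraries on the first (x axis) and second (y axis) principal components of log2(RPKM + 0.5). Colour gives the side of the embryo and marker shape the experiment, and the first component (75.9% of variance) separates experiment 1 from experiments 2 and 3.

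Which transcripts distinguish the organizer from the opposite side of the embryo is the question of the comparison between dorsal and ventral lips. Chordin, a secreted BMP antagonist made by the organizer, had the largest dorsal excess. Its transcripts Xelaev18027420m, Xelaev18027421m and Xelaev18029538m reached 230.5 ± 9.29, 166 ± 16.1 and 226 ± 36.8 RPKM in dorsal lips (SD, n = 3) against 0.185 ± 0.0877, 0.145 ± 0.0372 and 0.524 ± 0.304 RPKM in ventral lips. The log2 fold changes were 8.40 (SE 0.138), 8.01 (SE 0.13) and 7.81 (SE 0.243), with limma adjusted p of 1.49e-05, 1.49e-05 and 0.000213. Copies of the Nodal-related gene Xnr3, a direct target of maternal Wnt signalling, followed with log2 fold changes of 7.32 (SE 0.188) for Xelaev18018867m, 7.10 (SE 0.137) for Xelaev18018866m and 6.29 (SE 0.219) for Xelaev18018868m. The homeobox gene goosecoid (gsc.L) stood at 203 ± 17.2 RPKM in dorsal and 1.24 ± 1.014 RPKM in ventral lips (log2 fold change 7.01, limma adjusted p = 0.00214). The dorsally made BMP family ligand admp.S stood at 88.8 ± 33.1 against 0.480 ± 0.478 RPKM (6.55, limma adjusted p = 0.00347).

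On the ventral side, the leading transcripts were both copies of sizzled, a secreted feedback inhibitor that acts through Chordin-degrading proteases. Its copies szl.L and szl.S stood at 37.0 ± 16.5 and 33.9 ± 11.6 RPKM in ventral lips (SD, n = 3) and at 0.776 ± 0.507 and 1.02 ± 0.796 RPKM in dorsal lips. These are log2 fold changes of -4.86 (SE 0.413) and -4.63 (SE 0.522), with limma adjusted p of 0.0138 and 0.0413. The Wnt ligand wnt8a.S (-4.08, 0.661 ± 0.443 RPKM dorsal, 18.0 ± 0.501 ventral) and the BMP pseudoreceptor bambi.L (-3.81, 6.76 ± 1.14 RPKM dorsal, 104 ± 31.1 ventral) came next. The homeobox transcript VENTX (Xelaev18034617m) had a log2 fold change of -3.01, admp2.L of -2.68, and transcripts Xelaev18006666m and Xelaev18001123m, both named KLF2 after their human match, of -2.76 and -2.32. These last 6 transcripts had limma adjusted p between 0.00116 and 0.0454.

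**Figure D2:**
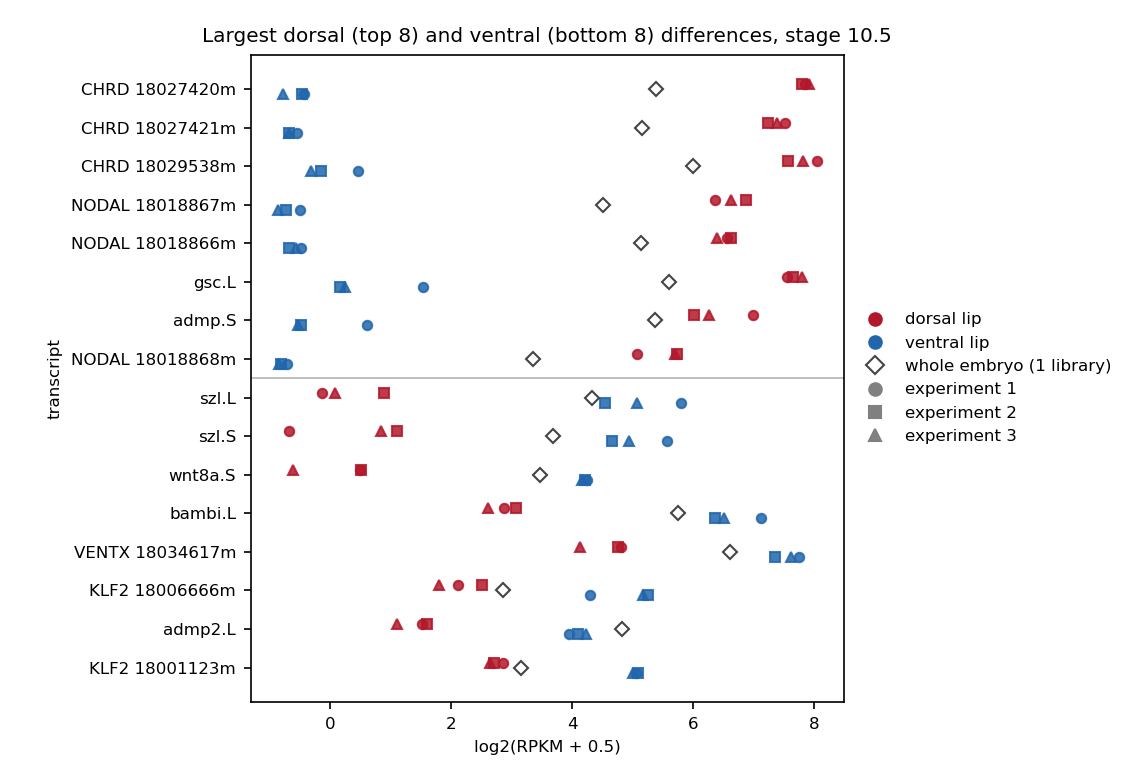
Expression (x axis, log2 of RPKM + 0.5) of the 8 transcripts with the largest dorsal and the 8 with the largest ventral excess (y axis, symbol with the transcript number where the file gives no frog symbol). Each filled point is 1 lip library, shaped by experiment, and the open diamond is the whole embryo library, and the 3 dorsal and 3 ventral values of each transcript do not overlap.

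Other transcripts past the test, chosen after their values were seen, included both copies of the winged-helix gene foxd3 and of lrig3. The log2 fold changes were 3.46 for foxd3.L, 3.27 for foxd3.S, 4.62 for lrig3.L and 3.03 for lrig3.S, and that of Xelaev18019203m, matched to the homeobox gene DMBX1, was 4.84. On the ventral side klf5.S (-1.23) and Xelaev18038210m, matched to the Notch pathway regulator NRARP (-1.13), passed too. In all, 54 of 16514 transcripts passed the limma test at an adjusted p of 0.05, 41 of them higher in dorsal and 13 in ventral lips, and 53 differed at least 2-fold. With the replicate block the number was 777, with 391 higher in dorsal and 386 in ventral lips, 254 of them at least 2-fold, and all 54 were among them. Experiments 2 and 3 alone, a subset chosen after seeing the data, gave 689 (449 dorsal, 240 ventral), also including the 54. The balance of directions changed with the fit, since experiments 2 and 3 with the block gave 724 dorsal and 918 ventral transcripts and limma voom on recovered reads with the block 553 and 1082, both also chosen after seeing the data. For all 54 the dorsal and ventral values did not overlap, which was true of 6.9% of all tested transcripts and of 10% by chance. The 54 were selected by a test on the same values, which favours such separation, so this is no further evidence. The count without the block moved with single libraries: it was 140 without ventral lip replicate 1, 27 without dorsal lip replicate 2, 24 without dorsal lip replicate 3, 25 without ventral lip replicate 2 and 21 without ventral lip replicate 3.

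Among the gene lists fixed before the data were examined, the Spemann organizer list differed most. Of its 44 measured members, 20 were higher in dorsal lips and 0 in ventral lips over all genes, and 36 and 3 when adjusted over the list alone. With the block, 33 and 2 passed. Beyond chordin, Xnr3, gsc and admp, the 20 included the BMP antagonist noggin (nog.L, log2 fold change 5.85, 39.2 ± 7.01 against 0.180 ± 0.0227 RPKM), the Wnt antagonist dkk1.S (4.57, 18.8 ± 5.41 against 0.296 ± 0.1), the Wnt receptors fzd8.L and fzd8.S (4.41 and 4.02) and the anterior endoderm homeobox gene hhex.L (4.43). The head inducer cerberus spread widely. Its copy cer1.S measured 109 ± 65.0 against 2.31 ± 3.79 RPKM (log2 fold change 6.14, limma adjusted p = 0.179, blocked 0.00435), and the Wnt antagonist frzb.L 54.0 ± 18.6 against 3.40 ± 2.86 RPKM (3.99, limma adjusted p = 0.0744, blocked 0.00118). The 2 members higher in ventral lips with the block were the notochord gene not.L (-0.45, limma blocked adjusted p = 0.0402) and dand5-like.1 (-0.25, blocked 0.0492), which entered the list by its human match CER1.

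Of 24 measured neural ectoderm genes, 3 were higher in dorsal lips over all genes and 11 when adjusted over the list alone, with 0 higher in ventral lips. With the block 11 passed. They included the OTX2 transcripts Xelaev18041108m (log2 fold change 5.56) and Xelaev18039840m (5.80), which the organizer list also holds, and the neural plate zinc finger gene zic1.S (1.89, 112 ± 6.33 against 30.2 ± 4.73 RPKM, limma adjusted p = 0.00711). Epidermal and superficial epithelium genes went the other way. Of 31 measured members, 1 was higher in ventral lips over all genes and 12 when adjusted over the list alone, and 12 ventral and 1 dorsal passed with the block. The homeobox gene dlx5.S stood at 6.52 ± 1.02 RPKM in dorsal and 33.8 ± 7.56 RPKM in ventral lips (log2 fold change -2.28, limma adjusted p = 0.0152). With the block the transcription factors TFAP2A (Xelaev18031635m, 15.8 against 65.7 RPKM, limma blocked adjusted p = 0.00128) and foxi1.S (0.760 against 4.22 RPKM, blocked 0.000715) were lower in dorsal lips too.

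The ventral center and BMP synexpression list had 40 measured members, of which 4 were higher in ventral and 1 in dorsal lips over all genes, 17 and 4 when adjusted over the list alone, and 18 and 4 with the block. The 4 were szl.L, szl.S, bambi.L and wnt8a.S, and the exception was the Notch effector hes1.L, which was higher in dorsal lips at 15.3 ± 1.81 against 4.71 ± 0.126 RPKM (log2 fold change 1.59, limma adjusted p = 0.0136). Of the 26 symbols written for this list 22 were found. Transcripts named VENTX after their human match, such as Xelaev18034617m, did not enter it, since the list was written with numbered symbols of that family. With the block the ligand bmp4.S was lower in dorsal lips at 9.24 ± 1.31 against 20.1 ± 0.902 RPKM (-1.09, limma adjusted p = 0.0606, blocked 0.00448). Of 18 zygotic Wnt targets and posterior genes, wnt8a.S alone passed over all genes, 0 dorsal and 2 ventral members passed when adjusted over the list alone, and with the block its partner wnt8a.L joined it (-4.02, 3.71 ± 2.69 against 58.3 ± 12.3 RPKM, limma blocked adjusted p = 0.0116). The Wnt target sp5l.L measured 287 against 203 RPKM and did not pass with the block (limma blocked adjusted p = 0.196), but passed in experiments 2 and 3 alone (0.00398). In ventral lip replicate 1 this list stood 2.27 higher in its median on the log2 scale than in the other ventral lips, with 15 of 18 members higher.

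Mesodermal and signalling lists held few differences over all genes. Of 30 pan-mesodermal genes, 0 passed limma without the block, 3 dorsal and 3 ventral passed when adjusted over the list alone, and 2 and 2 with the block. Those named by the rule were the T-box transcripts TBX3 (Xelaev18010379m, log2 fold change -1.92, limma blocked adjusted p = 0.00643) and TBX6 (Xelaev18001340m, -1.83, blocked 0.0183), and the growth factor fgf20.L (2.35, blocked 0.00974). In ventral lip replicate 1 the list stood 1.06 higher in its median on the log2 scale than in the other ventral lips, and in experiments 2 and 3 alone 12 members passed as higher in dorsal and 2 as higher in ventral lips. Of 29 Nodal and activin signalling genes 0 passed, 9 dorsal and 2 ventral when adjusted over the list alone, and 6 and 4 with the block, such as follistatin (fst.S, 2.81, limma blocked adjusted p = 0.00779) and the inhibitory smad7-like.L (-1.79, blocked 0.0337). Of 28 FGF signalling genes 0 passed, 7 dorsal and 0 ventral when adjusted over the list alone, and 8 and 1 with the block. Both copies of the FGF feedback inhibitor spry2 were higher in dorsal lips with the block, spry2.L at 30.1 ± 2.25 against 15.7 ± 2.82 RPKM (0.93, limma blocked adjusted p = 0.00534) and spry2.S with a log2 fold change of 0.80 (SE 0.136, blocked 0.0162).

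Of 34 convergent extension and axial mesoderm genes, 1 was higher in dorsal lips, over all genes and when adjusted over the list alone, and 8 dorsal and 1 ventral passed with the block. That member was the Wnt receptor transcript FZD7 (Xelaev18047362m, 106 ± 2.04 against 57.0 ± 2.19 RPKM, log2 fold change 0.89, limma adjusted p = 0.0138). Of 18 endoderm genes 0 passed limma, also when adjusted over the list alone, and 5 were higher in dorsal lips with the block, among them gata4.S (21.5 ± 3.28 against 6.35 ± 5.79 RPKM, limma blocked adjusted p = 0.0468) and the GATA5 transcripts Xelaev18046225m (1.16, blocked 0.0156) and Xelaev18043514m (2.14, blocked 0.0457). Of 17 retinoic acid pathway genes 0 passed, also over the list alone, and 3 were higher in dorsal lips with the block, including the retinoic acid synthesis enzyme aldh1a2.L (1.22, limma blocked adjusted p = 0.00288) and the degrading enzyme cyp26a1.L (0.34, blocked 0.0206). Of 15 germ plasm and vegetal maternal genes 0 passed, 1 dorsal over the list alone, and 1 dorsal and 2 ventral with the block. The dorsal member was otx1.S (1.14, limma blocked adjusted p = 0.0225) and the ventral ones nanos1.L (-1.31, blocked 0.0342) and the PLIN2 transcript Xelaev18010011m (-0.80, blocked 0.0351), while the germ cell gene dazl.L did not pass (-0.46, blocked 0.257). Of 151 ribosomal protein genes 0 passed in either fit, and their median log2 fold change was 0.062. Over all genes 515 transcripts had an unadjusted p under 0.05 without the block and 4335 with it, and limma voom on recovered reads called 46.

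**Figure D3:**
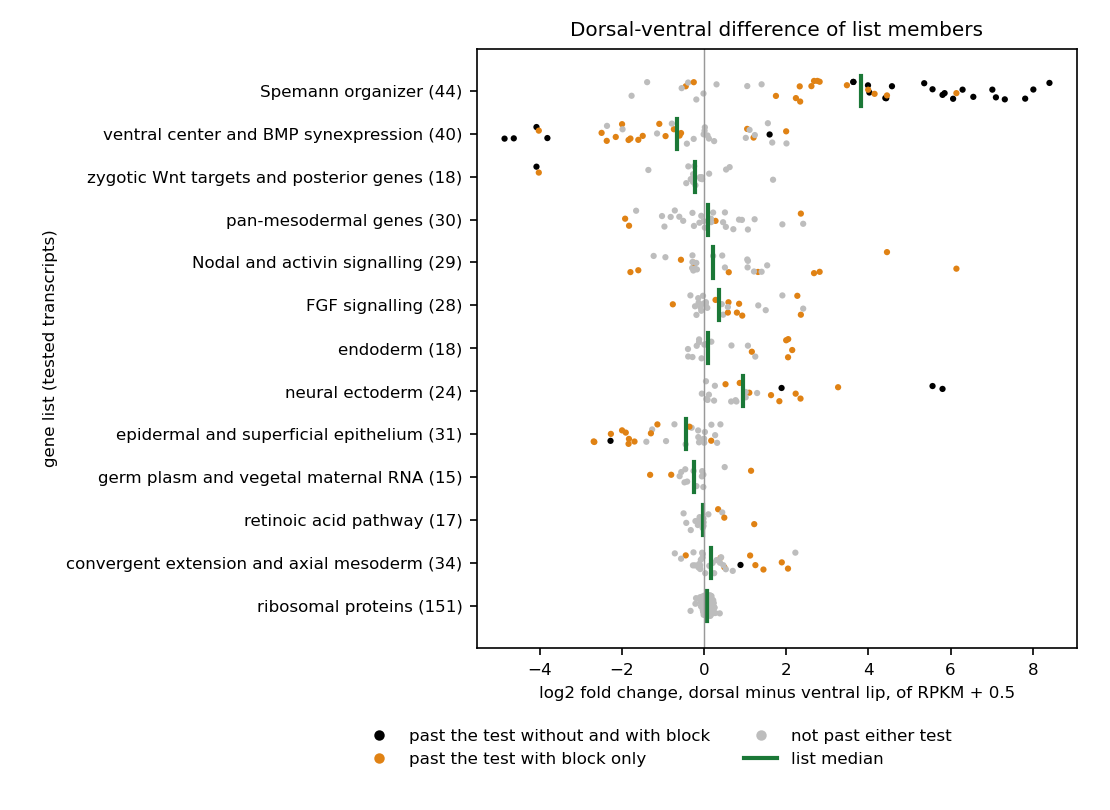
Log2 fold change between dorsal and ventral lips (x axis, of RPKM + 0.5) of each tested member of the 13 gene lists (y axis, number of members in brackets). Black points passed the limma test without and with the block, orange points with the block alone, and grey points in neither fit, while the green line is the list median, at 3.81 for the Spemann organizer and -0.67 for the ventral center and BMP synexpression list.

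Tested as sets against all other genes, 10 of the 13 lists differed (limma camera with a preset correlation of 0.01), in the dorsal direction for all but the ventral center and BMP list and the epidermal list. With this setting the other splits of the 6 lip libraries into equal groups also gave 3 to 11 lists. The number of lists alone therefore does not set the real split apart. With an estimated correlation 4 lists kept the call: the organizer and neural ectoderm lists (both adjusted p = 0.00561), and the FGF and epidermal lists (both adjusted p = 0.0433). The call was lost for the ventral center and BMP list (adjusted p = 0.128 with an estimated correlation), Nodal signalling (adjusted p = 0.0952), endoderm (adjusted p = 0.131), convergent extension (adjusted p = 0.103), the pan-mesodermal genes (adjusted p = 0.589) and ribosomal proteins (adjusted p = 0.327). In all these tests the ventral center and BMP list lacked the transcripts named VENTX after their human match. With an estimated correlation and the block none of the 13 passed, with the organizer list at adjusted p = 0.17 and the neural list at 0.197. The rotation test fry, which asks whether a list moves 1 way on balance, gave 5 lists without the block (organizer, neural, epidermal, FGF, and ventral center and BMP) and 3 with it (organizer 0.00282, epidermal 0.0123 and neural 0.0301). The posterior, germ plasm and retinoic acid lists did not pass camera (adjusted p = 0.219, 0.105 and 0.219), and the retinoic acid list had a median of -0.033 but a mean of 0.037 and an upward camera direction. In experiments 2 and 3 alone the germ plasm list passed in the ventral direction (adjusted p = 0.000216), and without ventral lip replicate 2 the pan-mesodermal list turned to a median of -0.12 and did not pass (adjusted p = 0.971).

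Xenopus laevis is allotetraploid, and many genes are present as an L and an S copy. The limma test of whether the copies differ in their dorsal to ventral change covered 3301 pairs. The Wnt antagonist frzb had the smallest p in the dorsal direction of the L copy. Its L copy measured 54.0 ± 18.6 RPKM in dorsal and 3.40 ± 2.86 RPKM in ventral lips (SD, n = 3) and its S copy 92.8 ± 32.8 and 22.1 ± 19.4 RPKM, a difference of 1.67 (SE 0.137) between their log2 fold changes (limma adjusted p = 0.0806, blocked 0.00976). For the Wnt antagonist dkk1 the S copy carried the larger dorsal excess, with log2 fold changes of 4.57 for dkk1.S and 1.75 for dkk1.L (difference -2.82, SE 0.327, limma adjusted p = 0.0885, blocked 0.00965). The copies of the mesodermal T-box gene brachyury measured 13.3 ± 4.39 dorsal and 28.1 ± 24.9 ventral RPKM for t.L and 65.6 ± 11.8 and 56.8 ± 48.2 RPKM for t.S (difference -1.24, SE 0.141, limma adjusted p = 0.0885, blocked 0.0133). For pafah1b3, zmiz2 and gadd45a the differences were 1.57, 1.85 and -1.25, with limma adjusted p of 0.0885 each and of 0.0259, 0.0288 and 0.00817 with the block.

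Over all pairs 0 passed limma without the block, with 105 at an unadjusted p under 0.05, and 74 passed with it, 30 with the L copy relatively higher in dorsal lips and 44 with it relatively higher in ventral lips. Without ventral lip replicate 1 the count was 14. Of 17 pairs with either copy past the dorsal to ventral test, 6 had both past it, all in the same direction. With the block there were 276 such pairs, 59 had both past it, and 58 of these went in the same direction. The exception was MGC89906, with log2 fold changes of 0.88 for the L copy and -0.95 for the S copy. The dorsal to ventral log2 fold changes of the copies correlated at 0.824 across pairs, which are not independent replicates. The median log2 ratio of L to S was 0.10 ± 0.03 in dorsal lips and 0.10 ± 0.04 in ventral lips (SD, n = 3) and 0.14 in the whole embryo. By experiment, it was 0.139 and 0.150 in the dorsal and ventral lip of experiment 1, to which the whole embryo belongs, and 0.0721 to 0.0889 in the lips of experiments 2 and 3. The difference between dorsal and ventral lips was smaller than the spread between replicates (exact permutation test, two-sided p = 0.8, where the smallest p this design allows is 0.1). That test did not pair the libraries by experiment, so the spread includes the difference between experiment 1 and the others.

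**Figure D4:**
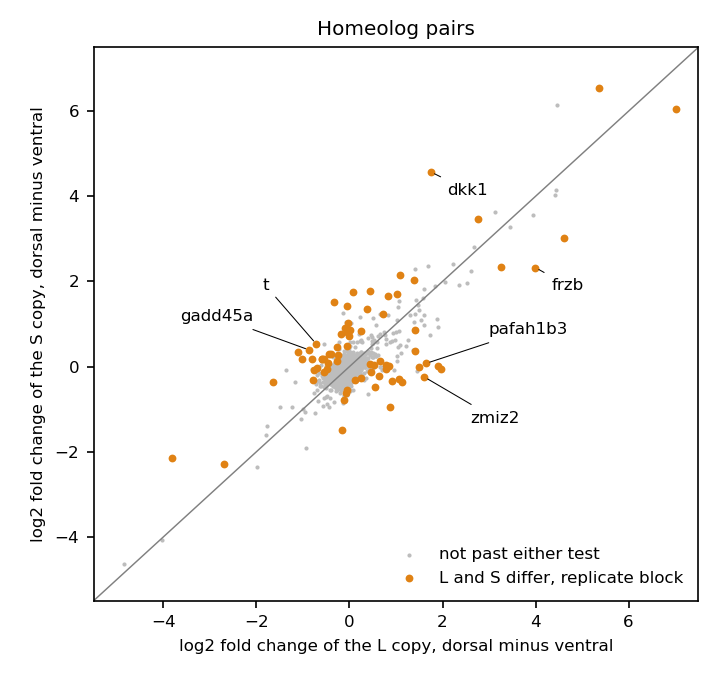
Log2 fold change between dorsal and ventral lips of the L copy (x axis) and the S copy (y axis) for 3301 homeolog pairs. Orange points are the 74 pairs whose copies differed with the replicate block, the line marks equal change, and labels give the 6 pairs named in the text.

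The whole embryo holds dorsal, ventral and all other tissue, so its level was compared with the lip means. Chordin Xelaev18027420m measured 41.2 RPKM in the whole embryo, gsc.L 47.7, szl.L 19.6 and bambi.L 53.2, each between the dorsal and ventral lip levels. The level lay between the lip means for 51 of the 54 transcripts past the test (94.4%, exact 95% interval 84.6 to 98.8%), and for 11.8% of all tested transcripts. The 54 were selected for a wide gap between the lip means, which holds any other value more often than a narrow one, so this contrast is no evidence beyond that selection. Of the 777 transcripts past the test with the block it did so for 41.96%. Since the whole embryo library belongs to experiment 1, it was also set against the lips of that experiment alone, chosen after seeing the data: the shares were 92.59% of the 54, 24.42% of all tested and 51.48% of the 777 transcripts. An exception was admp2.L, at 27.8 RPKM in the whole embryo against 2.18 ± 0.475 RPKM in dorsal and 16.5 ± 1.62 RPKM in ventral lips. The whole embryo has 1 library, so these values have no replicate check. The interval treats the 54 transcripts as independent, although copies of the same gene are among them, and covers no spread between samples.

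The authors' deposited table of dorsal transcripts held 315 entries, of which 291 were tested here, all 291 were in the same direction, 36 passed the test and 177 passed with the block. The authors' deposited table of ventral transcripts held 94 entries, of which 86 were tested here, all in the same direction, 12 passed and 60 passed with the block. In the authors' deposited table of all transcripts, 549 had an adjusted p under 0.05 and at least 2 times the ventral level in dorsal lips of experiments 2 and 3, more than the 315 listed as dorsal, and the further choice is not given in the sources used here. In the authors' deposited tables of dorsal and ventral signatures, with 107 and 70 transcripts, 90 and 68 were tested, all in the same direction, and 23 and 8 passed, or 85 and 60 with the block. All 54 transcripts past the test had an adjusted p under 0.05 in the authors' deposited table, which rests on the libraries of experiments 2 and 3 and gave 1107 such transcripts. These tables were chosen on these samples and are not independent evidence of direction. In the authors' deposited table of correlations to chordin over samples that include kinds not analysed here, the 41 dorsal transcripts had a median coefficient of 0.636 and the 13 ventral ones of -0.347, against 0.100 over all tested transcripts. To bambi, the medians in the authors' deposited table were -0.476 for dorsal and 0.692 for ventral transcripts, against -0.209 over all tested transcripts. These lips may be among the samples behind the coefficients, and the 41 and 13 include chordin and bambi.L themselves. The medians are therefore not independent evidence either.

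Another of the authors' deposited tables lists 744 transcripts more than 2 times higher in both lips of experiment 1 than in the whole embryo, as a response to injury. It includes immediate early genes, which answer within minutes to growth factors or wounding, and those named here were chosen after their values were seen. The transcription factor junb.L measured 0.252 RPKM in the whole embryo, 22.1 in the dorsal and 19.8 in the ventral lip of experiment 1, and between 0.195 and 0.496 in the 4 lips of experiments 2 and 3. The copy fos.S measured 1.42, 27.3 and 20.9 RPKM in experiment 1 and between 0.734 and 2.15 in the other lips. The zinc finger gene egr1.L measured 2.26, 23.1 and 18.8 RPKM in experiment 1, 8.17 and 8.09 in the dorsal and 1.38 and 1.23 in the ventral lips of experiments 2 and 3. Of 77 listed transcripts tested between dorsal and ventral lips, 0 passed limma without the block and 2 passed with it. The comparison with the whole embryo has 1 library in each arm and no replicate check.

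**Figure D5:**
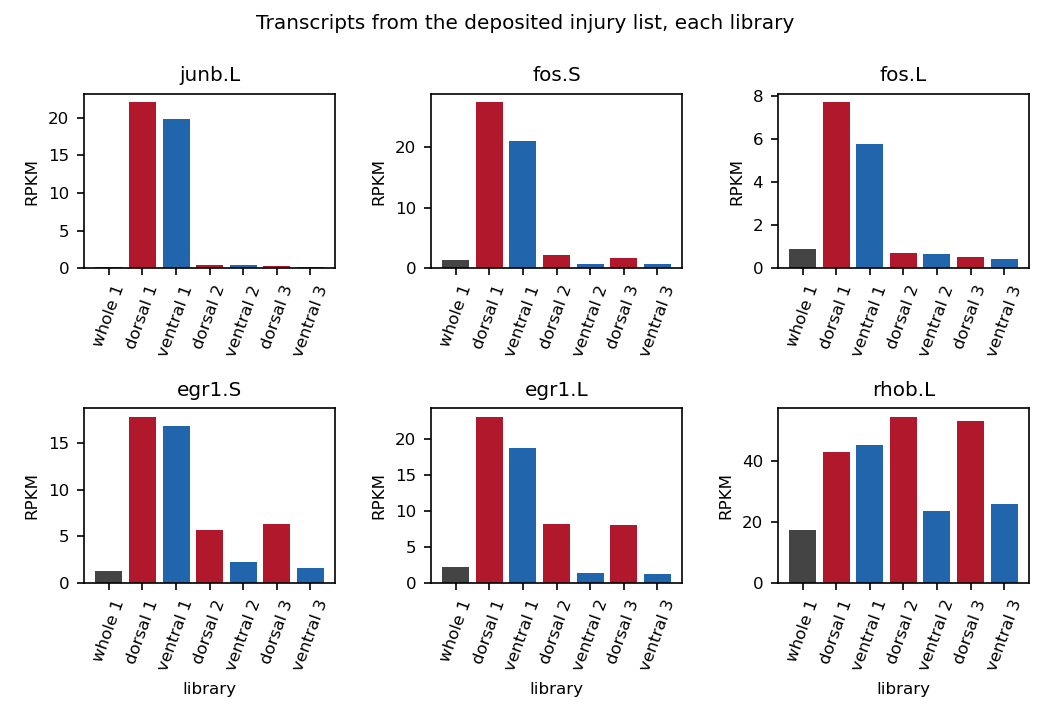
RPKM (y axis, from 0) of 6 transcripts of the authors' deposited injury list in the 7 libraries (x axis, whole embryo, dorsal lip or ventral lip with the experiment number). The bars of junb.L, fos.S and fos.L are highest in both lips of experiment 1, while rhob.L is highest in the dorsal lips of experiments 2 and 3.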

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

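Tests on experiments 2 and 3 alone, voom on recovered reads, an estimated correlation or fry together with the block, and the whole embryo level against the blocked calls or the lips of experiment 1 were chosen after seeing the data. The splits of the libraries were computed before their expected outcome was written down. Transcripts past the limma test numbered 54. With the replicate block there were 777, in experiments 2 and 3 alone 689 and with the block 1642, and with voom and the block 1635. Leaving out 1 library gave 21 to 140, the highest without ventral lip replicate 1. Other settings gave 46 to 60. Of 22 named transcripts past the test, leaving out 1 library ended the call of 1 to 11, with fewer samples in the test.

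Homeolog pairs past the test, 0 in the planned fit, numbered 74 with the replicate block, 115 and 238 in experiments 2 and 3 without and with it, 1 with a pseudocount of 0.1, 4 without a filter, 1 at a mean of at least 5 RPKM, and 0 to 14 when 1 library was left out. Transcripts of the authors' deposited dorsal and ventral tables past the test in the same direction, 48 together, numbered 237 with the block, 345 and 355 in experiments 2 and 3, 267 with voom and the block, 19 to 125 when 1 library was left out, and 377 by direction alone. Gene lists past the test, 10 with camera, numbered 4 with an estimated correlation, 5 with fry, 3 with fry and the block and 0 with an estimated correlation and the block, and 8 to 12 elsewhere. The median log2 ratio of L to S moved from 0.10 to 0.16 when either copy had to reach 1 RPKM, which admits pairs with a silent copy. The share of transcripts with a whole embryo level between the lip means was 41.96% for the blocked calls. The pan-mesodermal list turned from an upward to a downward direction without ventral lip replicate 2 (median -0.12, against 0.52 without ventral lip replicate 1) and without a filter (-0.031), neither past the test. Its median was also below 0, with an upward camera direction and not past the test, with L and S summed (-0.066) and with voom and the block (-0.038), and the call was lost without dorsal lip replicate 2 (adjusted p = 0.0901) and with quantile normalisation (0.0658) too. The cause was not tested.

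The block changed no list's camera call with the preset correlation. Single named transcripts and named homeolog pairs kept their direction in each setting run for them. The summed L and S values were not run for single transcripts, and quantile normalisation, limma without trend and voom were not run for pairs. Without the block 10 splits of the 6 lip libraries are too few for a share under 0.05: the real split gave 54 transcripts, 10 lists and 0 pairs, and the highest other split 0 transcripts, 11 lists and 0 pairs. Of the 10 splits, 1 gave as many transcripts, 3 as many lists and 10 as many pairs, the real split included. The split with 11 lists sets dorsal 1 with ventral 2 and 3, so that experiments 2 and 3 stay whole in their contrast and experiment 1 is turned, and another with 10 sets both lips of experiment 1 with dorsal 2. With the block, the real split gave 777 transcripts and 74 pairs and each of the other 3 gave 0, while the lists were 10 against at most 9. These 4 splits are also too few for a share under 0.05. In each of the other 3 the dorsal to ventral difference adds to the residual spread, so 0 calls there cannot check the 777. The same holds for the other splits without the block, where 0 transcripts cannot check the 54. Depth limits low transcripts, since 1 read over 1 kb is worth up to 0.0369 RPKM.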

Other observations

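Tests of older embryos, dorsal tissue, endoderm, handling in experiments 2 and 3 and a shared dissection effect were chosen only after the result was seen, as were the transcripts named here. Some transcripts were present in experiment 1 and nearly absent in experiments 2 and 3, or the reverse, alike in both lips. Below 0.5 RPKM in the 3 libraries of experiment 1 and at 5 RPKM or more in the 4 others were 16 transcripts, and 11 showed the reverse, while 0 did so between experiments 2 and 3. The carnosinase gene cndp1.L, a member of the endoderm list, measured 0.0798 RPKM in the whole embryo, 0.142 and 0.0705 in the lips of experiment 1, and between 25.7 and 26.7 in the other 4 lips. The betaine metabolism gene bhmt.L measured between 12.2 and 13.1 RPKM in experiment 1 and between 0.0671 and 0.204 in the other lips. For the kinase stk33.L the values were 0.109 to 0.319 and 10.9 to 12.1 RPKM, while its partner stk33.S was measured at 11.1 to 12.3 RPKM in experiment 1 and at 18.2 to 18.3 RPKM in experiments 2 and 3.

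Ventral lip replicate 1 also held more posterior and mesodermal transcripts than the other ventral lips. The list of zygotic Wnt targets and posterior genes stood 4.83 times higher in its median, with 15 of 18 members higher, and the pan-mesodermal list 1.06 higher on the log2 scale with 26 of 30, above all of 10000 random lists of like expression. This was not particular to them: the organizer, ventral center and BMP, and epidermal lists also lay above all random lists, with smaller medians of 0.53, 0.70 and 0.45 on the log2 scale, and the Nodal, endoderm and retinoic acid lists above at least 99.85% of them. Nor was it confined to the ventral lip: in the dorsal lip of experiment 1 the organizer list lay above all random lists, and the ventral center and BMP, endoderm, neural, retinoic acid and epidermal lists above at least 99.77% of them. There the posterior and pan-mesodermal medians differed by 0.22 and -0.08 on the log2 scale. The Nodal list was lower there, with a median of -0.5 on that scale and 8 of 29 members higher. Ribosomal proteins lay above at most 0.01% of random lists in both lips of experiment 1. Random lists ignore that L, S and tandem copies of a gene can move together, so these percentages are too extreme. The homeobox gene hoxd1.L measured 6.89 RPKM in ventral lip 1 and 0.202 and 0.445 in the others, cdx4.S 9.80 against 0.334 and 0.415, and mespb.S 52.7 against 2.45 and 6.28. Other mesodermal genes were close to each other, with eomes.L at 70.7, 68.3 and 82.0 RPKM and fgf8.L at 23.3, 22.1 and 25.7 RPKM. These ratios compare single libraries and have no replicate check.

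The libraries of experiment 1 stood apart, with 853 transcripts over 2 times higher and 2156 over 2 times lower than in experiments 2 and 3. A bias by transcript length is argued against as the whole cause, since a smooth trend on recovered length explained 2.13% of the variance of this difference and 2567 transcripts stayed over 2 times apart without it. Handling of the lips of experiment 1 is argued against as the main cause by the whole embryo of that experiment, which was not dissected: its level lay nearer to experiment 1 for 94.6% of these transcripts, and for 78.65% of all tested transcripts. Handling of the lips of experiments 2 and 3 would also give a high share, and so would the batch that the whole embryo shares with experiment 1, so it stays open. That handling, the parents, the age of the embryos, the library batch and the sequencing lane may each differ between experiment 1 and the others and cannot be told apart by this design, and no biological explanation was tested.

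In ventral lip replicate 1, 84 of 444 transcripts with a dorsal excess in experiments 2 and 3 had at least 3 times the share of the dorsal level, with a median of 63.1%, such as lhx1.L at 38.8% against 7.20% and 8.61%. Dorsal lip tissue of the same make-up as the dorsal samples is argued against by chordin. Its share was 0.203% with an upper 95% limit of 0.236% that covers counting error only. The share was 0.138% and 0.0843% in experiments 2 and 3, and all 3 lie far under the shares of these transcripts. The 84 were selected for a raised share, and 1 marker cannot argue against a part of the dorsal lip low in chordin. Among the 84 were the organizer transcripts gsc.L, at 1.29% against 0.307% and 0.311%, and cer1.S, at 3.64% against 0.0894% and 0.232%. Endoderm in the sample may account for part of the pattern, but its members went both ways, with mixer.L at 161 RPKM against 46.2 and 56.6 in the other ventral lips and sox17a.L at 41.4 against 51.2 and 48.3, and all 18 are also measured in the lips of the other experiments. The shift of the list between experiments, taken as ventral minus dorsal, had a median of 0.021 (log2), under the limit written as evidence against endoderm. A list median does not exclude an effect on single members such as mixer.L, so endoderm stays open for part of the pattern. Older embryos in experiment 1 might also raise posterior genes, and the smaller of the 2 lip medians of that list was 0.22, between the values set for and against, while the exact place of dissection was not tested.

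Of the transcripts in the authors' deposited injury table, 575 had 1 to 5 whole embryo reads, and the median was 2 reads. Counting noise was tested on all transcripts with a whole embryo read, listed or not, of which 702 were over 2 times higher by RPKM in both lips of experiment 1. It may account for most of the 674 with under 50 whole embryo reads, since unchanged simulated libraries gave 524. It cannot account for the 28 with at least 50 reads, among them fos.S, fos.L, egr1.S and egr1.L, for which the simulation gave 0. More transcripts of that depth went the other way, with 157 over 2 times lower in both lips of experiment 1 than in the whole embryo. Of the 32 listed transcripts with at least 50 whole embryo reads, the 28 among them, 15.6% were over 2 times above the whole embryo in all 4 lips of experiments 2 and 3, and 20 were so in none of these 4 lips. These shares alone do not decide on a dissection effect shared by all experiments, since experiments 2 and 3 have no undissected library. For junb.L (22.1 and 19.8 RPKM in the lips of experiment 1, 0.195 to 0.496 in the other lips) and fos.L (7.71 and 5.78 against 0.443 to 0.721) the levels argue against a shared effect as the cause of the rise in experiment 1, as do those of fos.S. For egr1 it stays open, since the levels in experiments 2 and 3 differed by lip and copy. Against 2.26 RPKM in the whole embryo, egr1.L measured 8.17 and 8.09 RPKM in their dorsal lips but 1.38 and 1.23 in their ventral lips. With 1.26 RPKM in the whole embryo, egr1.S measured 5.70 and 6.28 in the dorsal and 2.29 and 1.59 in the ventral lips. The time between dissection and lysis in experiment 1 stays a candidate explanation of the junb, fos and egr1 levels and was not tested.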
